A study of Mus musculus with 8 samples.

How the data were processed

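Total RNA from the cerebellum of male mice aged 8 to 10 weeks was hybridised to Affymetrix mouse exon arrays, 1 array per sample. The series holds 8 arrays, 4 from mice with the R306C substitution in MeCP2 and 4 from wild-type littermates. Group and replicate number were taken from the sample titles, and 0 columns of the table were left without a sample. Per the labels' protocols, RNA was purified with Trizol and RNeasy columns with a DNase step, then fragmented and labelled with the Ambion WT Expression Kit. The values deposited by the authors are on a log scale, taken here as log2 from their range, with 1 value per transcript cluster and array. The log base, summary method and normalization were not given in the sources used here. The genome build named in the submitters' processing notes is mm9. No scanner files were used here. The array means and medians were nearly equal while the quartiles differed slightly, so the deposited arrays are on a similar scale and differences in total signal are not visible in these values.

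The table held 17958 transcript clusters, called probes here. The platform annotation paired 15621 of them with 1 gene symbol, 1370 with several and 967 with none. Entrez identifiers of 15560 single-gene probes matched the RefSeq gene table, whose assembly is GRCm38.p6, and 0 symbols needed an update. Genes are named from single-gene probes only. Because that assembly is not the build of the processing notes, no gene lengths or distances were taken from it. It served only for names and, by the order of its gene starts, for which genes lie beside each other. The planned slope of expression on gene length and the planned comparison of long with short genes were therefore not run. Mecp2 was not among the genes named for the probes, so its level is not analysed here.

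Probes whose mean over the 8 arrays lay at or above the 25th percentile of probe means, a floor of 5.91 on the log2 scale, were tested. This left 13468 probes and, with the brightest probe per gene, 11757 genes. R306C minus wild type was fitted with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with a mean trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Replicate numbers were not used as a block, because the labels do not say that equal numbers mark related animals. Of the 32 gene lists fixed beforehand, 30 had at least 5 measured genes, while those of unipolar brush cells and red blood cells had fewer. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the 30 lists. The lists covered very long genes, cerebellar and other brain cell types, receptors, channels, adhesion and synaptic genes, stress, activity and hormone responses, metabolic and housekeeping sets, genes linked to MeCP2 in earlier work and genes flanking Mecp2. The list of very long genes was written from general knowledge of genes with very large transcription units, not from a length table. A score per array was the median over a list of each gene's log2 value minus its mean over the 8 arrays, less the same median over all 11757 genes. Scores were compared with exact two-sided permutation tests over all 70 relabelings, whose smallest possible p is 0.0286. Nothing beyond the labels says that the replicates are separate animals, so p-values of single probes and of scores measure the spread between these samples. Camera compares a list with the other genes. At the preset correlation of 0.01 its p does not cover the spread of a whole list between arrays.

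The gene lists, tests, naming rule and most other settings tried were fixed before the data were examined. Named genes were single-gene probes past the threshold with no overlap between the genotypes, up to 12 per direction by fold change. Where fewer than 6 passed in a direction, the 6 with the smallest p were added as values. To these came the 6 very long genes and the 4 members of each other list with the smallest p. The other settings were quantile normalization, median centring, other filters on dim probes, other variance priors, array weights, a replicate block, averaging a gene's probes and leaving out each array. Chosen after seeing the data were a fit on the arrays within the wild-type range of the brainstem marker median score, a block of samples numbered 1 and 2 against 3 and 4, and the axon guidance list without very long genes.

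The fit was tested on simulated data with the spread of these 13468 probes. It recovered 22 of 50 probes changed by 0.3 on the log2 scale, 41 of 50 changed by 0.5, 50 of 50 changed by 0.8 and 50 of 50 changed by 1.2. It made 6 false calls beside them. The simulation changed 200 probes, whereas 9 passed in the arrays. More changed probes make the adjusted threshold easier to pass, so recovery in the arrays is likely lower than these rates. With no change simulated the list test called 0 lists, and a list shift of 0.1 was recovered as 0.101. Genes were simulated as independent, so this does not cover the correlation between genes in the arrays, where the other 34 splits of the 8 arrays called a median of 6 lists. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.071. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.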

Results

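Expression in the cerebellum was compared between mice with the R306C substitution in MeCP2 (4 arrays) and wild-type littermates (4 arrays), all aged 8 to 10 weeks. MeCP2 is a methyl-DNA-binding protein abundant in neurons, mutated in Rett syndrome, and the substitution lies in the region through which it recruits the NCoR/SMRT co-repressor. The arrays were similar in overall signal, with medians from 7.33 to 7.36 on the log2 scale. Pearson correlations between arrays ranged from 0.987 to 0.996 across probes, which are not independent replicates. The genotype labels describe males, and the Y-linked genes Kdm5d and Eif2s3y were at similar levels in both genotypes. Kdm5d averaged 8.03 ± 0.056 in wild type and 8.04 ± 0.16 in R306C (log2, SD, n = 4 each), and Eif2s3y 9.04 ± 0.16 and 9.03 ± 0.26. The Mecp2 transcript was not analysed here.

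The first question was which single genes differed between the genotypes. Ntng1, which encodes netrin-G1, a membrane-anchored relative of the netrin guidance cues, rose most clearly in R306C. It went from 8.25 ± 0.12 in wild type to 9.08 ± 0.035 in R306C (log2, SD, n = 4 each), which is 1.77-fold (log2 fold change 0.82, SE 0.061, adjusted p = 0.000432 by limma), with wild-type replicate 1 apart from its group at 8.08. Pnck, a kinase of the calcium/calmodulin-dependent kinase I family, rose 1.56-fold from 8.70 ± 0.046 to 9.34 ± 0.10 (log2 fold change 0.64, SE 0.056, adjusted p = 0.00115). Pnck lies close to Mecp2, within the 25 annotated protein-coding genes on one side of it. The endoplasmic reticulum genes Pdia4 and Atp2a3 fell, as did Cnih2, an auxiliary subunit of AMPA-type glutamate receptors.

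Smaller increases past the threshold were found for 3 more genes. Osbpl3, of the oxysterol-binding protein family, rose by 0.48 on the log2 scale (SE 0.066, adjusted p = 0.0365). Pbx3, a homeodomain transcription factor, rose by 0.43 (SE 0.049, adjusted p = 0.00892), and Sipa1l1, a Rap GTPase-activating protein of the synapse, by 0.31 (SE 0.041, adjusted p = 0.0338). Pdia4, a protein disulfide isomerase, fell by 0.44 (SE 0.065), Atp2a3, a calcium pump of the endoplasmic reticulum, fell by 0.42 (SE 0.062) and Cnih2 fell by 0.38 (SE 0.055), each with an adjusted p of 0.0451. For all 8 of these genes, the 4 R306C arrays lay on one side of the 4 wild-type arrays. Other genes with the smallest p in each direction did not pass. Coro6, which encodes a coronin, had a log2 fold change of 0.27 (adjusted p = 0.0755). The potassium channel subunit Kcng4 had -0.56 (adjusted p = 0.0755), the chaperone Hspa5 -0.52 (adjusted p = 0.0755) and Trank1 -0.29 (adjusted p = 0.121). Kcng4 (-0.62) and Hspa5 (-0.58) passed without R306C replicate 1. Coro6 (adjusted p = 0.0347) and Kcng4 (adjusted p = 0.0202) passed with samples numbered 1 and 2 blocked against 3 and 4, a choice made after seeing the data.

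**Figure D1:**
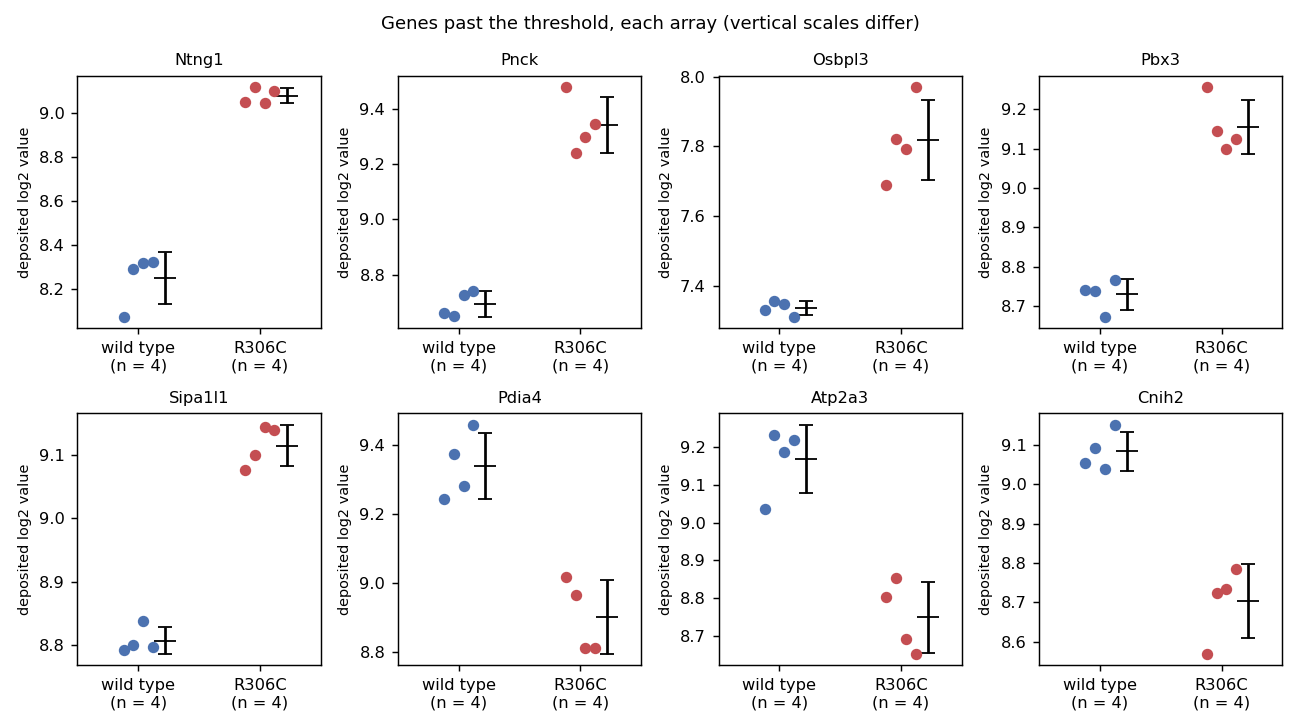
Deposited log2 value (vertical axis, a separate scale per panel) of each array for the 8 single-gene probes past the threshold, by genotype (horizontal axis). Points are arrays, and the black bar and whiskers are the mean and SD of 4 arrays. In every panel the R306C points lie wholly above or wholly below the wild-type points, and Ntng1 averages 8.25 in wild type and 9.08 in R306C.

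In total, 9 of 13468 probes passed an adjusted p of 0.05 with limma, 6 higher and 3 lower in R306C, of which 1 higher probe matches several genes and is not named. At an unadjusted p under 0.05 there were 1011 probes, 446 higher and 565 lower. Chance alone would give 673 on average, with a wider spread where probes are correlated. No overlap between the genotypes was seen for 640 probes, or 4.75%, against 2.86% by chance. Of the 35 splits of the 8 arrays into 4 and 4, 7 gave as many probes by either count (up to 2224 and 1322, the latter a comparison chosen after seeing the data), so neither excess is beyond that of other groupings. Changes of more than 1 on the log2 scale were seen for 0 probes. With each array left out, Ntng1 and Pnck passed every time, Pbx3 in 7 of 8 (adjusted p = 0.0575 without R306C replicate 4) and the other 5 genes in 1 or 2 of 8, and the count was 23 without R306C replicate 1, 4, 5 and 2 without R306C replicates 2, 3 and 4, and 5, 4 and 3 without wild-type replicates 1, 2 and 4. It was also 5 (5 higher, 0 lower) after quantile normalization, 9 (7 higher, 2 lower) after median centring, 6 (6 higher, 0 lower) without a variance trend, and 20 (12 higher, 8 lower) with samples numbered 1 and 2 set apart from 3 and 4 as a block, a choice made after seeing the data.

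The next question, which the title of the series raises, was whether long genes shift as a group. Very long genes rose together in R306C. Of 122 measured members, 109 were higher and 13 lower, with a median log2 fold change of 0.094 (camera adjusted p = 1.99e-20, and adjusted p = 0.0464 with an estimated correlation). The examples with the smallest p were Prkce, a protein kinase C isoform (0.24, SE 0.041), the synaptic vesicle calcium sensor Syt1 (0.20, SE 0.035), the contactin Cntn6 (0.31, SE 0.061), the cell adhesion molecule Opcml (0.23, SE 0.051), the reelin adaptor Dab1 (0.18, SE 0.041) and the calcium channel subunit Cacna2d1 (0.28, SE 0.064). Adjusted over the list alone, 16 members rose and 2 fell, while 0 passed when adjusted over all genes tested. The 2 that fell were the calcium channel gene Cacna1e (-0.18) and Dpp10 (-0.15), a potassium channel partner chosen after its values were seen.

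Every R306C array scored above every wild-type array for the very long genes. The score averaged -0.050 ± 0.015 in wild type and 0.044 ± 0.027 in R306C (log2, SD, n = 4 each), a difference of 0.095 (exact permutation p = 0.0286, the smallest possible, and 0.214 after adjustment over the 30 lists). By the median score of the brainstem markers, R306C replicates 2 and 3 lay above every wild-type array, while R306C replicate 4 lay above every wild-type array for 4 of the 10 markers, Slc17a6 among them, and below every one for 2, as counted after the values were seen. On the 6 arrays within the wild-type range of that median score, which keep R306C replicate 4 and were chosen after seeing the data, the difference was 0.12 (exact permutation p = 0.0667, the smallest possible with 6 arrays), and 2 probes and 7 lists passed. Within samples numbered 1 and 2 the score difference was 0.096, and within those numbered 3 and 4 it was 0.094, with 2 arrays per genotype in each.

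**Figure D2:**
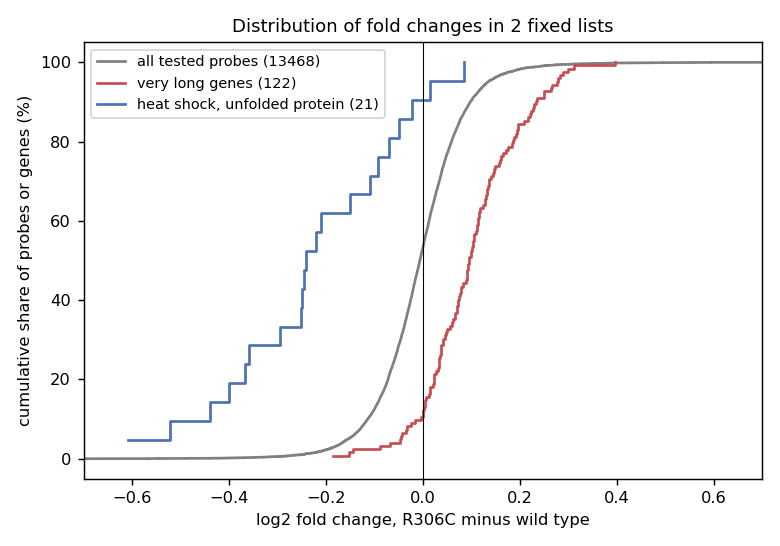
Cumulative share in percent (vertical axis) of log2 fold changes, R306C minus wild type (horizontal axis), for all 13468 tested probes (grey), the 122 very long genes (red) and the 21 heat shock and unfolded protein genes (blue). The red line lies to the right of the grey one, with 109 genes above 0, and the blue line to its left, with 19 genes below 0.

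Genes of the heat shock and unfolded protein response fell in R306C. Of 21 measured members 19 were lower, with a median log2 fold change of -0.24 (camera adjusted p = 3.81e-13, and adjusted p = 0.0464 with an estimated correlation). Adjusted over the list alone 11 members fell and 0 rose, and 1 of them, Pdia4, also passed over all genes tested. Among the 11 were Hspa5 (-0.52, SE 0.085), the main chaperone of the endoplasmic reticulum, Manf (-0.36, SE 0.070), a secreted factor of the same compartment, and the small heat shock protein gene Hspb1 (-0.37, SE 0.079). The list score was 0.12 ± 0.053 in wild type and -0.13 ± 0.061 in R306C (log2, SD, n = 4 each), without overlap between arrays (difference -0.25, exact permutation p = 0.0286, the smallest possible, and 0.214 after adjustment over the 30 lists). Choroid plexus markers, from a secretory tissue, moved the same way, as described with the cell types.

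Axon guidance and adhesion genes were mostly higher. Of 65 measured members 44 were higher and 21 lower, with a median log2 fold change of 0.066 (camera adjusted p = 3.42e-06). This call was lost with an estimated correlation (adjusted p = 0.175) and with fry (adjusted p = 0.0532). Adjusted over the list alone 10 members rose and 0 fell, and 1, Ntng1, passed over all genes. Cntn6 (0.31), the axonal contactin Cntn1 (0.18, SE 0.035) and the ephrin Efna5 (0.28, SE 0.064) were among the 10. The list shares 13 measured members with the very long genes. Without them, a choice made after seeing the data, its median was 0.016 (camera adjusted p = 0.0101). With the very long members kept and the 50th percentile filter, the median of the list was 0.043.

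Among cerebellar neurons, Purkinje cell markers were lower and granule cell markers showed no call. Of 21 Purkinje markers 16 were lower, with a median of -0.054 (camera adjusted p = 0.00499, fry adjusted p = 0.0141, but adjusted p = 0.106 with an estimated correlation). The Purkinje score was 0.042 ± 0.038 in wild type and -0.027 ± 0.031 in R306C (log2, SD, n = 4 each). The arrays of the genotypes overlapped (exact permutation p = 0.0571, and 0.343 after adjustment over the lists). Kcng4 (-0.56), the phospholipase Plcb3 (-0.19), the kinase Stk17b (-0.28) and Icmt (-0.17) fell when adjusted over the list alone, and 0 members passed over all genes. Of 17 granule neuron markers 10 were higher, with a median of 0.013 (camera adjusted p = 0.497), and the granule cell gene Cbln1 differed by 0.045 (SE 0.032, adjusted p = 0.862). Of 14 inhibitory interneuron markers 9 were lower, with a median of -0.041 (camera adjusted p = 0.297). Gad1, which encodes a GABA-synthesizing enzyme, fell when adjusted over the list alone (-0.18, SE 0.037), while the vesicular GABA transporter Slc32a1 did not pass (-0.21, SE 0.065).

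Lists chosen as markers of tissue next to the cerebellum varied between arrays. All 10 choroid plexus and ependyma markers were lower in R306C, with a median of -0.33 (camera adjusted p = 0.00179). This call was lost with an estimated correlation (adjusted p = 0.539), with fry (adjusted p = 0.633) and without wild-type replicate 2 (median -0.21, adjusted p = 0.0997). It was also lost on the arrays within the wild-type range of the brainstem score, a choice made after seeing the data (median -0.17, camera adjusted p = 0.194). The median was -0.53 without R306C replicate 1 and -0.56 without wild-type replicate 4. The choroid plexus score was 0.16 ± 0.48 in wild type and -0.18 ± 0.42 in R306C (log2, SD, n = 4 each), a difference within the spread between arrays (exact permutation p = 0.371). Of 10 brainstem neuron markers 7 were higher, with a median of 0.074 (camera adjusted p = 0.0400, and adjusted p = 0.539 with an estimated correlation). The median was 0.045 without R306C replicate 2, 0.034 without R306C replicate 3 and 0.043 without wild-type replicate 3, each without a call, 0.12 without wild-type replicate 2 and 0.11 without wild-type replicate 4, both with the call kept, and -0.034 with R306C replicates 2 and 3 both left out, a choice made after seeing the data. Slc17a6, a vesicular glutamate transporter on the brainstem list, differed by 0.74 (SE 0.25, adjusted p = 0.475). Whether its transcripts came from outside the cerebellum was not tested.

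**Figure D3:**
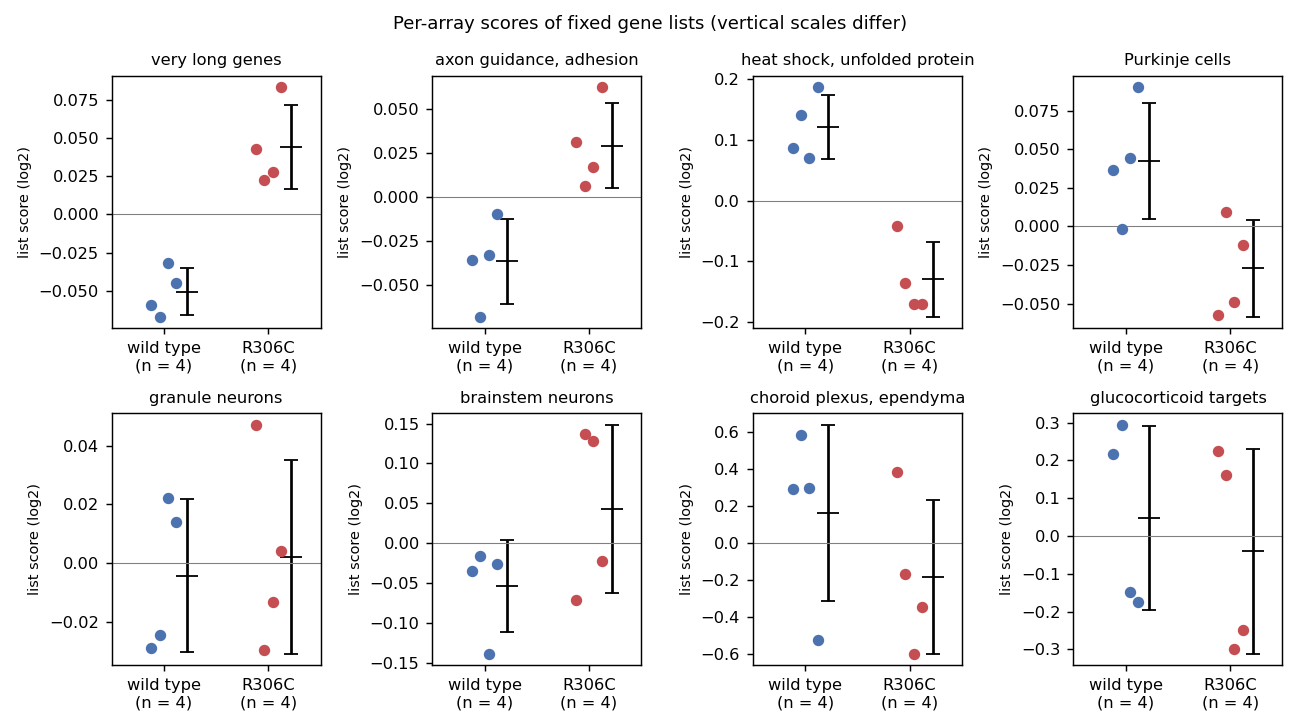
Score per array (vertical axis, log2, a separate scale per panel) of 8 gene lists in wild type and R306C (horizontal axis). Points are arrays, and the black bar and whiskers are the mean and SD of 4 arrays. The genotypes do not overlap for the very long, axon guidance and heat shock lists, while those of choroid plexus and glucocorticoid targets overlap widely.

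Further lists passed camera with small shifts and lost the call with an estimated correlation. Of 18 glutamate receptor genes 13 were higher, with a median of 0.037 (camera adjusted p = 0.0400, and adjusted p = 0.539 with an estimated correlation), and the AMPA receptor gene Gria2 differed by 0.15 (SE 0.044, adjusted p = 0.362). Of these 18 genes, 7 are also among the very long genes. Of 16 glucocorticoid targets 15 were lower, with a median of -0.12 (camera adjusted p = 0.0400, and adjusted p = 0.669 with an estimated correlation). The mitochondrial kinase gene Pdk4 differed by -0.36 (SE 0.11, adjusted p = 0.387). Of 19 cholesterol synthesis genes 16 were lower, with a median of -0.065 (camera adjusted p = 0.0405, and adjusted p = 0.634 with an estimated correlation), and Ebp, a sterol isomerase, fell when adjusted over the list alone (-0.27, SE 0.062). These calls depended on which arrays were fitted, and with one left out the medians reached 0.065, -0.22 and -0.11, respectively. The glutamate receptor call was lost without R306C replicate 1 (median 0.021) or 4 (0.032) and without wild-type replicate 1 (0.022) or 2 (0.036). The glucocorticoid call was lost without R306C replicate 3 (-0.047) or 4 (-0.055) and without wild-type replicate 1 (-0.071) or 2 (-0.024), and the cholesterol call without R306C replicate 1 (-0.027) or 2 (-0.035) and without wild-type replicate 3 (-0.033) or 4 (-0.043). Processing mattered as well. With the 50th percentile filter all 3 calls were lost (camera adjusted p = 0.104, 0.400 and 0.0904). The glutamate receptor and cholesterol calls were also lost without a variance trend (0.0579 and 0.0508) and with array weights (0.0651 and 0.307). All 3 calls were kept with samples numbered 1 and 2 blocked against 3 and 4, a choice made after seeing the data (adjusted p = 0.0334, 0.000320 and 0.0170).

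Genes that earlier work on other samples linked to MeCP2 moved in both directions. Of 19 measured 6 were higher and 13 lower, with a median of -0.074 and no call (camera adjusted p = 0.282). Adjusted over the list alone, the transcription factor Mef2c (0.26, SE 0.051) and the splicing factor Rbfox1 (0.14, SE 0.038) rose, while Gad1 and the creatine synthesis gene Gamt (-0.28, SE 0.061) fell. Of 11 genes flanking Mecp2, 8 were lower, with a median of -0.060 (camera adjusted p = 0.105). Their score was 0.022 ± 0.0075 in wild type and -0.024 ± 0.018 in R306C (log2, SD, n = 4 each) without overlap (exact permutation p = 0.0286, the smallest possible, and 0.214 after adjustment over the lists).

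No call was made for the lists that remained. Microglia markers were mostly lower, 13 of 17 with a median of -0.060 (camera adjusted p = 0.0532), as were 11 of 11 oligodendrocyte precursor markers (median -0.071, adjusted p = 0.104). Microglia passed after median centring (-0.052) and without R306C replicate 2 (-0.12) or 3 (-0.077) or wild-type replicate 3 (-0.15), and oligodendrocyte precursors without R306C replicate 2 (-0.090). Meningeal markers had a median of 0.026 (adjusted p = 0.0534), and Ogn, an extracellular matrix gene (0.59, SE 0.13), rose when adjusted over the list alone. Meninges passed without R306C replicate 1 (0.064) or 4 (0.059) or wild-type replicate 1 (0.046) or 2 (0.056). Median log2 fold changes were -0.0030 for mature oligodendrocytes, -0.017 for astrocytes and Bergmann glia and 0.0045 for endothelium and pericytes, where the smooth muscle actin gene Acta2 rose (0.55, SE 0.11) and the pericyte gene Rgs5 fell (-0.16, SE 0.044) when adjusted over the list alone. They were 0.0063 for potassium channels, -0.013 for sodium and calcium channels, 0.067 for GABA and glycine receptors, 0.0043 for synaptic vesicle genes and 0.00059 for neuropeptides. They were 0.0067 for immediate early genes, -0.0043 for circadian clock genes, -0.030 for the interferon response and -0.027 for co-repressor and DNA methylation genes. Ribosomal protein genes had -0.0067 and oxidative phosphorylation genes -0.013. Oligodendrocytes passed without wild-type replicate 4 (0.041), and immediate early genes (0.084) and neuropeptides (0.078) without R306C replicate 1.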

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

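The tests of granule markers, brainstem tissue, choroid plexus and neighbours of Mecp2 were chosen after the results they bear on had been seen. The splits, the test of array scale and the test of immediate early genes were set beforehand, but the condition on the standard error in the last was not.

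Chance was not excluded for the count of 9 probes, since 3 of the 35 splits of the 8 arrays into 4 and 4 gave as many. The highest other split gave 104 probes and set the samples numbered 1 and 2 of both genotypes against those numbered 3 and 4, which points to a structure of the samples by number. With that division as a block, a choice made after seeing the data, 20 probes passed, including all 9. Nor was chance excluded for the count of 9 lists, which 10 of 35 splits reached, with 11 as the highest of the others.

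Very long genes were higher on all 4 R306C arrays. Their score difference was larger than in any other split (0.095 against 0.067 for the highest other), as the lack of overlap requires. That comparison adds nothing to the exact permutation p of the score (0.214 after adjustment over the lists). Array scale or expression level is argued against by the shift over genes matched on expression after quantile normalization, 0.0938 (exact permutation p = 0.0286, the smallest possible). A higher share of RNA from granule neurons is argued against by their markers, which do not cover a rise of other neurons alone. The mean log2 fold change of the granule markers was 0.0090, against a median of 0.094 for the very long genes. Its SE of 0.0137 was taken over 17 genes and does not cover the spread between arrays. The granule score per array was -0.0042 ± 0.026 in wild type and 0.0022 ± 0.033 in R306C (log2, SD, n = 4 each), a difference of 0.0064 against 0.095. Brainstem tissue as followed by the marker Slc17a6 is argued against as the whole source, though not as a part of it. With the level of Slc17a6 in the fit, the difference stayed at 0.0804 (SE 0.0211). That of the glycine receptor gene Glra1 fell from 0.92 to 0.18. Glra1 had the largest log2 fold change of all tested probes, so its fall is no separate check. Only Slc17a6 was fitted, while of the 10 brainstem markers 7 were higher and 3 lower in R306C. Sncg, among the higher ones, lay above every wild-type array on all 4 R306C arrays, so its level cannot be told apart from genotype. A release of long genes from MeCP2-dependent repression is a hypothesis these values leave open, and differences in RNA integrity between the groups were not tested.

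Heat shock and unfolded protein genes were lower on all 4 R306C arrays. Their difference was larger than in any other split (0.25 against 0.19 for the highest other), as the lack of overlap requires. It adds nothing to the exact permutation p (0.214 after adjustment over the 30 lists). Less choroid plexus, a tissue rich in secretory chaperones, is argued against as the whole cause, though not as a part of it. The unfolded protein score rose with the choroid plexus score among R306C arrays (slope 0.142) and fell with it among wild-type arrays (slope -0.0701), and with the R306C slope removed from all arrays the difference went from -0.251 to -0.202 (SE 0.0558). Handling stress or activity at dissection cannot be told apart from genotype, because the immediate early gene score differed by 0.0034 with a standard error of 0.123, too wide to decide. The rule set beforehand used only the size of that difference and the share of members that were lower, 10 of 21. By that rule alone the explanation would have been argued against, but it leaves out the spread between arrays. An effect of genotype on the folding machinery remains a possible explanation, found and tested on the same arrays.

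Pnck was higher on all 4 R306C arrays and lies near Mecp2. A general rise of genes beside Mecp2 is argued against by the median of the 25 other measured neighbours, which was -0.0470. A block of neighbouring sequence carried along with the targeted allele remains possible but was not decided. Of those 25 neighbours, 5 (20%) had an unadjusted p under 0.05 against 7.51% of other genes (one-sided Fisher's exact p = 0.0361). All 5 were lower, opposite to Pnck. The Fisher test counts genes measured on the same arrays as independent, so its p does not cover the spread between arrays. An effect of the R306C protein on Pnck itself remains open and untested.

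Single arrays stood apart from their group in 9 of 202 checks, where chance would give 10.1, by the gap to the nearest array as a share of the group's range. Ntng1 in wild-type replicate 1 read 8.08 against 8.29 to 8.32 (share 0.873). Folr1, a choroid plexus gene, in wild-type replicate 4 read 7.41 against 8.48 to 8.62 (share 0.883). Kcna2 in R306C replicate 4 read 10.98 against 10.91 to 10.92 (share 0.887). The endothelium and pericyte score of R306C replicate 4 was 0.074 against -0.0090 to -0.00060 (share 0.898). In wild-type replicate 3, the brainstem score was -0.14 against -0.035 to -0.016 (share 0.847), the potassium channel score -0.059 against 0.0010 to 0.0069 (share 0.911) and the array median 7.338 against 7.354 to 7.355 (share 0.966). The array mean of R306C replicate 2 was 7.387 against 7.359 to 7.363 (share 0.844). The mean correlation of wild-type replicate 2 with the other arrays was 0.991 against 0.992 to 0.993 (share 0.859).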

How the results depend on the processing

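Very long genes and heat shock and unfolded protein genes kept their calls in all 21 and all 20 alternatives that touched those lists, with medians from 0.080 to 0.11 and from -0.28 to -0.20. Ntng1 and Pnck kept theirs in all 18 run on probes, Pbx3 in 16, and Osbpl3, Sipa1l1, Pdia4, Atp2a3 and Cnih2 in 6 to 8. The probe count of 9 became 18 with array weights, 5 without the dim filter and 5 after quantile normalization. It ranged from 2 (without R306C replicate 4) to 23 (without R306C replicate 1) with an array left out, and the causes were not tested. The list count of 9 became 4 with the 50th percentile filter, 2 with an estimated correlation and 3 with fry, the last a test of another question. The very long gene score kept its direction, at 0.0793 to 0.106 with an array left out. The samples were not treated as paired by replicate number, since pairing was set to need every same-numbered correlation over 0.1. Correlations of same-numbered deviations were 0.23, 0.52, -0.15 and 0.23. Only in number 2 did both arrays correlate best with each other. These values do not exclude a structure shared by some numbers. With the replicate block 9 probes passed (5 shared, with Osbpl3, Sipa1l1, Pdia4 and Atp2a3 lost), 10 lists passed, and the very long gene difference was 0.0946 (exact permutation p = 0.125, the smallest possible). Meninges (adjusted p = 0.0263), Ogn (adjusted p = 0.0205) and Kcng4 (adjusted p = 0.0268) also passed with it.

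Other alternatives were chosen after seeing the data. With samples numbered 1 and 2 blocked against 3 and 4, 20 probes and 9 lists passed, and the very long gene difference was 0.0946 (exact permutation p = 0.0556, the smallest possible). It was 0.0979 with samples numbered 1 and 2 alone and 0.104 with 3 and 4 alone, both rescored (exact permutation p = 0.333, the smallest possible). On arrays within the wild-type range of the brainstem median score, R306C replicate 4 among them, it was 0.12 (exact permutation p = 0.0667, the smallest possible), 2 probes passed, and the brainstem list reversed to -0.0343. Fewer relabelings account for those p-values. Of the 21 lists without a call, 13 changed sign somewhere, in 52 of 459 values. A length slope and long minus short genes were not run, nor was the Mecp2 level, another pseudocount on values already logged, or a robust prior for lists.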

Other observations

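Glucocorticoid target scores were higher in samples numbered 1 and 2 than in those numbered 3 and 4, as seen after the values had been examined, and that difference was not tested. The glucocorticoid target score was 0.22 and 0.29 in wild-type replicates 1 and 2 and -0.15 and -0.17 in replicates 3 and 4. In R306C it was 0.22 and 0.16 in replicates 1 and 2 and -0.30 and -0.25 in replicates 3 and 4. Fkbp5, a chaperone gene induced by glucocorticoids and chosen after its values were seen, read 7.86 and 7.91 in wild-type replicates 1 and 2 and 6.91 and 6.71 in replicates 3 and 4. In R306C, Fkbp5 read 7.70 and 7.54 in replicates 1 and 2 and 6.62 and 6.49 in replicates 3 and 4. The activity-induced nuclear receptor gene Nr4a1 went the other way, at 7.61 and 7.70 in wild-type replicates 1 and 2, 8.51 and 8.36 in replicates 3 and 4, 7.76 and 7.62 in R306C replicates 1 and 2, and 9.34 and 9.25 in R306C replicates 3 and 4. The score of all immediate early genes was -0.15, 0.032, -0.0086 and 0.10 in wild-type replicates 1 to 4 and -0.30, -0.029, 0.20 and 0.13 in R306C replicates 1 to 4. The labels give no date or batch for these samples.

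Slc17a6, from the brainstem list, and Glra1 were also uneven among the R306C arrays, and the tissue they came from was not tested. Slc17a6 read 6.72, 7.18, 7.89 and 8.02 in R306C replicates 1 to 4 and 6.43 to 7.07 in wild type. The glycine receptor gene Glra1 read 6.57, 7.23, 7.77 and 7.77 in R306C and 6.07 to 6.98 in wild type. R306C replicate 1, within the wild-type range for both, had a very long gene score of 0.043, while the highest wild-type score was -0.032. Of the 10 brainstem markers, however, R306C replicate 1 lay above every wild-type array for 2 and below every one for 3.

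Within the heat shock and unfolded protein list, a division made after seeing the values set genes of the endoplasmic reticulum apart from cytosolic ones. All 10 endoplasmic reticulum members were lower, with a median log2 fold change of -0.33, against 5 of 6 cytosolic heat shock genes (median -0.15) and 4 of 5 genes of the ATF4 branch (median -0.071). The hypothesis that the endoplasmic reticulum members may have fallen more than the cytosolic ones was tested by the difference of their scores per array. That difference was -0.165 (exact permutation p = 0.171), so the tests do not decide it.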
